A study of Drosophila melanogaster with 3 samples.

How the data were processed

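ChIP-seq with an antibody against GFP was done on 3 biological replicates of D. melanogaster embryos of 0 to 24 hours, which express CG15514 with a C-terminal eGFP tag. Chromatin was fragmented by sonication to 200 to 800 bp, per the labels. The replicate numbers come from the labels, and all 3 samples form 1 group.

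The deposited files are peak lists in narrowPeak format on dm6 and dm3. Per the deposited descriptions, each replicate list was made from that replicate's alignment and a control alignment, the same one for all 3 replicates of a build. The pooled list was made from the alignments of the 3 replicates together with that control, and the thresholded list from the replicate lists and the pooled list. The replicate and pooled lists hold 30000 entries each, peaks and background together, as input for IDR, a method that keeps peaks of reproducible rank. Each height is a signal value that the authors' peak caller set against the control; it is deposited without a scale between lists and was therefore compared only within a list. The significance column is a −log10 q value in the deposited lists, and it is capped: 6701 of the 8708 thresholded peaks on dm6 (77%) share the maximum of 4.127, so peaks were ranked by signal. The last column used is the position of the summit in the interval, as deposited. All 8708 thresholded peaks on dm6 are the 8708 strongest entries of the pooled list. In 93 cases a further summit shares the interval of another. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. No list from a mock or input sample was used here. The lists hold no read counts, so the depth per sample is unknown, and intervals on shares cover counting error over peaks or genes alone.

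Coordinates are those of the dm6 lists, written from 1. The reference was the Release 6 genome sequence of D. melanogaster, the assembly that dm6 names, with Ensembl 115 annotation of FlyBase release 6.54. The dm3 lists were used for counts and shares per chromosome, without converting coordinates. Peaks on X, 2L, 2R, 3L, 3R and 4 were used, which was every entry of the dm6 lists. A promoter was defined as 500 bp around any annotated TSS of any gene. The annotation class of a summit was the first that applied of promoter, 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. Transposable elements in the annotation were not counted as genes.

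Support of a thresholded peak in a replicate meant a summit within 100 bp among the 8708 strongest entries of that replicate. Support, promoter shares and annotation classes were set against 1000 random circular shifts of the summits along each arm. Shares have 95% Clopper-Pearson intervals. The difference in median signal used 100000 permutations. Chromosome arms were tested with the exact binomial test against their length. Gene lists were tested with Fisher's exact test, two-sided, against other protein-coding genes, or all genes for the non-coding lists. Preset motifs were sought as exact matches on either strand within 100 bp of the summit. The control was 1 window per peak from the same arm and promoter class, in the same bin of 2 percentage points of GC content, and more than 500 bp from any thresholded interval, drawn without replacement. All 8708 peaks had a control. The 8-mers were counted within 50 bp of the 1000 strongest summits and in their controls, with reverse complements merged. Benjamini-Hochberg adjustment was made over arms, classes, lists, motifs or all 32896 8-mers, and the threshold was an adjusted p of 0.05. Values per replicate are means and SDs over the 3 replicate lists, each taken to the same number of strongest entries.

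The gene lists, motifs and tests were fixed before the data were examined. The named genes were CG15514, the gene of the nearest TSS within 500 bp for each of the 20 strongest peaks with any others sharing it, and, for each list, up to 4 members with the highest promoter signal. In a list where fewer than 50% of the members had a promoter peak, up to 2 members without one were added in alphabetical order. Of the names in the lists, 25 were matched through a synonym and 13 matched no gene. Genes and sites named outside this rule are said to have been chosen after their values were seen.

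The tests were tried on simulated data. A planted 8-mer was recovered when it was in 10% or 5% of 1000 windows and missed at 2%, with 0 other 8-mers called. A planted DRE was recovered at 10%, 5% and 2% of 8708 windows. A list of 30 genes bound at 80% among genes bound at 43% was called in 14 of 20 simulations, and a list of 20 genes in 12 of 20, with 1 and 2 calls of other lists over all simulations. Lists that shared 60% of summits were read as 60.2% on average and called in 20 of 20 simulations, and unrelated lists were called in 0 of 20. An X raised by 1.2 times was called, with 1 other arm called beside it.

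Alternatives fixed in advance were a summit distance of 50 bp, overlap of intervals by 1 bp or by 50% of each, lists of 50% or 200% of the length, TSS distances of 250 and 1000 bp, protein-coding genes alone, the stronger 50% of peaks, each replicate left out in turn, genes with a TSS within 1000 bp of another gene's left out, motif windows of 50 and 200 bp, flanking windows 500 bp away as control, all peaks in the 8-mer search, start sites as the expectation for arms, the dm3 list, and a stricter threshold on the significance column. With a replicate left out, the thresholded list was not made again. Its peaks were kept if both other replicates supported them, so this setting changes 2 things at once. In the motif tests, every alternative but flanking windows also drew its control windows again, so a call can change with the draw as well. As most values of the significance column are tied, the stricter list was the peaks at its maximum. Added after seeing the data were motif controls at the peaks' own distances from a TSS, agreement on the dm3 lists, and promoter shares and gene lists without the 200 strongest peaks. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.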

Results

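The series mapped the chromatin sites of a single protein, the product of the Drosophila melanogaster gene CG15514, in whole embryos. The flies carried CG15514 fused at its C-terminal end to eGFP, a green fluorescent protein that serves as a tag. Chromatin immunoprecipitation with an antibody against GFP was followed by sequencing (ChIP-seq), so that a peak marks DNA recovered with the tagged protein. Mixed-sex embryos of 0 to 24 hours were used, and the 3 samples formed 1 group of 3 biological replicates. There was no second condition, so the comparisons the design allows are between peaks and the rest of the genome, between gene groups, and between replicates. Each replicate had its own list of 30000 entries, a further list of 30000 entries came from the pooled replicates, and the authors' thresholded list held 8708 peaks on genome build dm6. The lists give peak heights and no read counts, so the sequencing depth of each sample is unknown.

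The tagged gene itself had no peak. CG15514 (FBgn0039712) lies on 3R from 29860055 to 29861494 on the minus strand. No summit of the thresholded list, the pooled list or any of the 3 replicate lists fell in the gene or within 2000 bp of it. The nearest thresholded summit, at 3R position 29857531, was 2524 bp away, with a signal value of 888.1 and rank 647 of 8708.

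All 20 peaks of the highest signal had an annotated transcription start site (TSS) within 500 bp, at distances from 14 to 157 bp. The first was the promoter of CG11454 (FBgn0031224, gene at 2L 143323 to 144227), with a peak from 142605 to 143957, its summit at 143283 and a signal of 70620. That summit also lay within 500 bp of a TSS of CG31974, in an annotated intron. The second was at an internal start site of aux (FBgn0037218, gene at 3R 4211783 to 4227518), which encodes auxilin, a clathrin uncoating factor. Its summit at 4220961 was intronic and had a signal of 64036. CG12091 (3L, summit 1536921) followed with 63950, CG10366 (2L, summit 19584178) with 55473 and Rilpl (X, summit 1393005) with 55164. The CG10366 summit was shared with PCNA2 and that of CG12091 with pns.

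SREBP, the transcription factor of lipid synthesis, had a signal of 50354 at 3L position 19793851, within 500 bp of its own TSS and of those of CG42637 and Gyc76C. Dph1, an enzyme of diphthamide synthesis, had 50212, and Polr1B, a subunit of RNA polymerase I, had 48903. The summit between Axn, the Axin scaffold of Wnt signalling, and the ribosomal protein gene RpS28a had 48442, at 3R position 30022802. Sbat (with Prx6a), CG7222 (with CG12341) and Sec63 (with pst) had 47783, 46403 and 45287. CG5521 (with the gustatory receptor gene Gr97a), CASK and the succinate dehydrogenase subunit gene SdhA (with asRNA:CR45925) had 44916, 44370 and 44282. The splicing factor gene Sf3a1 (with Irc) had 43663, zf30C 43606 and JTBR (with CG42676) 43119. PrBP (with Trs23) and the Hippo pathway gene kibra closed the 20 with 40147 and 40083. In 13 of the 20, more than 1 gene had a TSS within 500 bp, so the peak could not be given to 1 gene alone. The lowest rank of any of the 20 in a replicate list was 24.

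Peak height fell without a gap from the strongest peaks to the weakest. The signal was 17455 at rank 110, 5074 at rank 200, 5044 at rank 201, 2461 at rank 273, 643.9 at rank 1000 and 118.9 at the last thresholded rank, 8708, against 70620 at the top. The median over the thresholded list was 236.4, with quartiles of 160.3 and 390. Peak width had a median of 424 bp and quartiles of 351 and 424 bp. In replicates 1, 2 and 3 the signal fell from 17539, 17285 and 35891 at the top to 1421, 1192 and 2573 at rank 200. It stood at 28.6, 31.46 and 68.17 at rank 8708. Signal values come from the authors' peak caller and are used here only within a list. The 200 strongest peaks are a set taken by height from this continuous curve, and its boundary was chosen after the heights were seen.

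**Figure D1:**
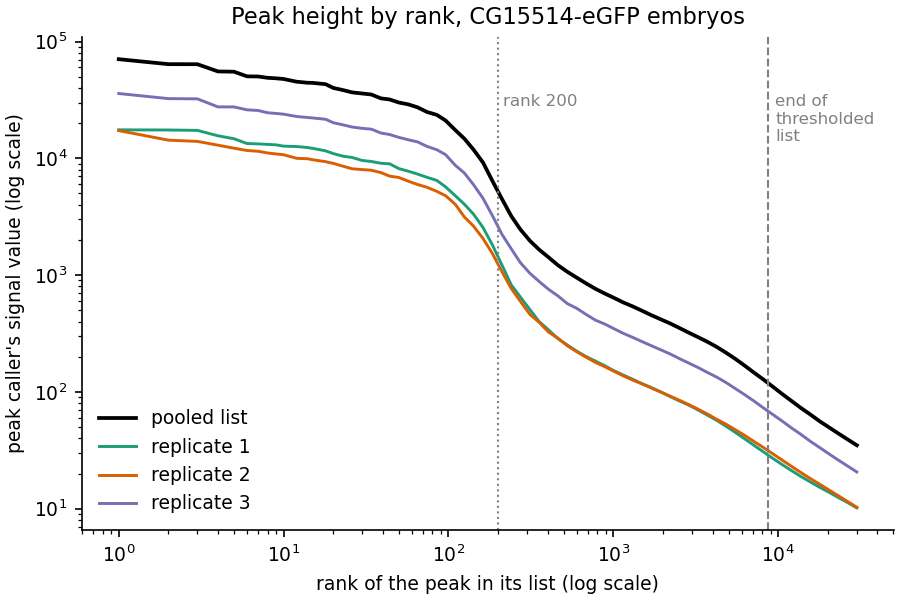
Signal value (log scale) against the rank of the peak (log scale) for the pooled list and the 3 replicate lists, with dotted and dashed lines at rank 200 and at the end of the thresholded list. All 4 curves fall without a gap, the pooled list from 70620 at rank 1 to 5074 at rank 200.

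A short sequence, GAAC(C/T)AG, recurred at these strongest summits. It was found within 100 bp of the summit in 17 of the 20 strongest peaks, the exceptions being those at aux, Polr1B and Sec63. At CG11454 the nearest match lay 11 bp from the summit, in the sequence AGTAACTAGTTCTTAAA (2L 143286 to 143302, intronic). At CG12091 it lay 1 bp from the summit, in TTTCGGAACCAGTACAA (3L 1536914 to 1536930, intergenic). At CG5521 and Gr97a it lay 23 bp away in GGTGCGAACTAGTTCCG (3R 26966855 to 26966871), and at zf30C 11 bp away in CCGAACTGGTTCGTGGC (2L 9758275 to 9758291). At SdhA the sequence was AACCGGAACTAGTTCAT (2R 19395984 to 19396000), 49 bp from the summit. The sequences at CG5521, zf30C and SdhA hold the 10-base palindromic form GAAC(C/T)(A/G)GTTC. Both forms were chosen after the search without preset motifs, described next, had been seen.

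The search over all 32896 8-mers found 44 that were more frequent within 50 bp of the 1000 strongest summits than in matched control windows, and 0 that were less frequent (Fisher's exact test, adjusted over all 8-mers). The first was ACTGGTTC, in 66 peaks against 3 control windows (6.6% against 0.3%, exact adjusted p = 2.22e-12). ACTAGTTC was in 60 against 2 (exact adjusted p = 5.93e-12), CTGGTTCC in 46 against 1 and AACTAGTT in 48 against 2. A separate family matched the DNA replication-related element (DRE), a core promoter element bound by the factor Dref. Of this family, ATCGATAG was in 65 peaks against 7 windows and TATCGATA in 68 against 9. CAGCCCTG, in 31 against 0 (exact adjusted p = 2.69e-06), belonged to neither family. Each of the 44 was put in the first family that it matched on either strand. Of them, 25 held GAAC(C/T) or (C/T)(A/G)GTT, 13 others held the ATCGAT or TATCG core and 6 held neither. The 25 include AACTATCG, which also holds TATCG, because its reverse complement CGATAGTT holds TAGTT. With all thresholded peaks in place of the 1000 strongest, 574 8-mers were more and 292 less frequent, and the first was TATCGATA (4.88% against 0.54%). With flanking windows as the control 158 were more and 10 less frequent, and ACTGGTTC stayed first.

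The GAAC family was concentrated in the strongest peaks, and the DRE was not. GAACYAG (Y for C or T) lay within 100 bp of 71.5% of the 200 strongest summits (95% Clopper-Pearson interval 64.7% to 77.6%). The share was 13.5% at ranks 201 to 1000, 4.17% at ranks 1001 to 4000 and 3.97% at ranks 4001 to 8708, against 2.61% of control windows. The palindrome GAACYRGTTC fell from 37% of the 200 strongest to 3.5%, 0.467% and 0.552%, with 0.0459% of control windows. TATCGATA went from 11.5% to 9.5%, 10% and 5.48%, with 0.93% in controls. GGTCACAC, the core of the Ohler 1 element bound by M1BP, had its highest share, 9.23%, at ranks 1001 to 4000, against 5% in the 200 strongest and 0.62% of controls.

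**Figure D2:**
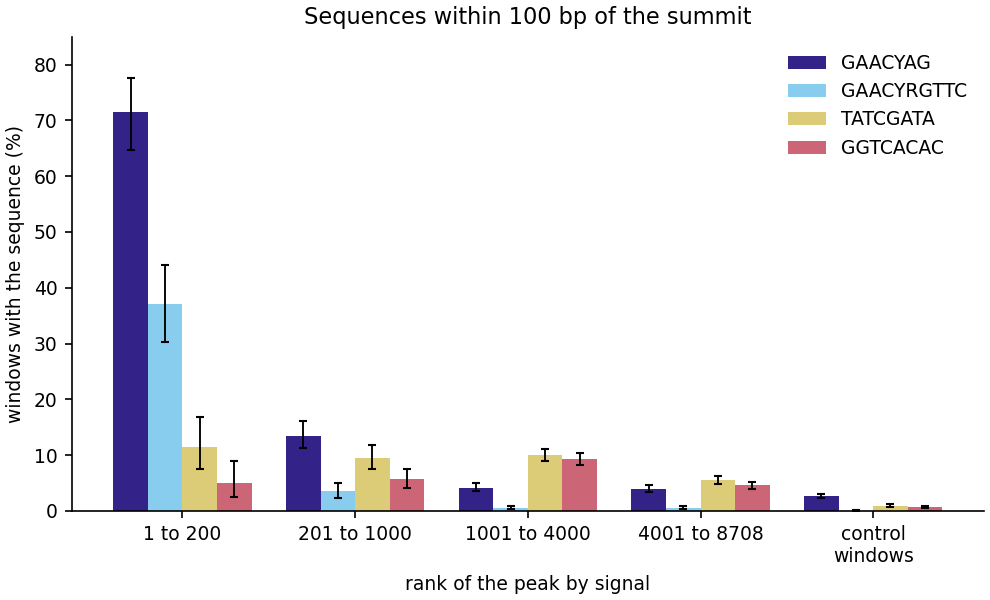
Share of peaks (%) with each of 4 sequences within 100 bp of the summit, by rank of the peak, and in the matched control windows; error bars are 95% exact binomial intervals. GAACYAG drops from 71.5% in the 200 strongest peaks to 3.97% in the weakest, while TATCGATA stays between 5.48% and 11.5%.

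Of the 18 motifs fixed in advance, 8 were more frequent within 100 bp of thresholded summits than in control windows matched on chromosome arm, GC content and promoter class. The DRE was in 7.55% of peaks against 0.93% of controls (odds ratio 8.69, adjusted p = 2.55e-116, Fisher's exact test throughout). Ohler motif 1 was in 4.38% against 0.31% (odds ratio 14.7, exact adjusted p = 4.35e-82), Ohler motif 6 in 1.6% against 0.333% (odds ratio 4.86) and Ohler motif 7 in 19.3% against 5.78% (odds ratio 3.9). The insulator motifs followed: the CTCF core had 2.01% against 0.333% (odds ratio 6.14, exact adjusted p = 2.01e-26) and the BEAF-32 sequence CGATA 37.7% against 23.6% (odds ratio 1.96). CGATA is part of the DRE. The E-box of Ohler motif 5 was in 13.4% against 7.22% and the GAGA element, bound by Trl and Clamp, in 4.57% against 2.11%. All 8 passed in every setting, but odds ratios moved. That of the DRE was 12.2, 13.7 and 16.9 without replicates 1, 2 and 3, in peaks supported in both other replicates. That of Ohler motif 1 was 22.8 without replicate 2, 33.7 in the stronger 50% of peaks and 8.43 with controls at the peaks' own distances from a TSS, chosen after seeing the data. Ohler motif 7 had 6.03 in the stronger 50%, and Ohler motif 6 had 10.8 against flanking windows. The CTCF core had 13.6 in windows of 50 bp, 9.27 in the stronger 50% and 3.82 against flanking windows. The GAGA element went from 2.22 to 1.18 against flanking windows (4.57% against 3.92%, exact adjusted p = 0.0161). Shares in the strongest 8708 entries of each replicate list were close to these, with a DRE share of 7.49% ± 0.359 and an Ohler motif 1 share of 4.46% ± 0.219 (mean and SD, n = 3).

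The initiator, in 18.6% of peaks against 20.5% of controls (odds ratio 0.89, exact adjusted p = 0.00455), and the motif of the early embryonic activator Zelda, in 0.792% against 1.31% (odds ratio 0.602, exact adjusted p = 0.00205), were less frequent at peaks. Both calls depended on the setting. In what follows, "without" a replicate means the thresholded peaks supported in both other replicates. The list itself was not made again, so the setting also asks for support that the full list does not. Control windows were drawn again as well, so a changed call cannot be laid to the replicate alone. For Zelda without replicate 1, for example, peaks had 0.806% and the new controls 0.899%. The initiator passed in windows of 200 bp, in the stronger 50% of peaks and without replicate 1 (exact adjusted p = 0.00126, 0.00106 and 0.00917). It was also less frequent with controls at the peaks' own distances from a TSS, chosen after seeing the data (18.6% against 23.3%, exact adjusted p = 7.65e-14). It did not pass in windows of 50 bp (exact adjusted p = 0.535) or without replicates 2 and 3 (exact adjusted p = 0.113 and 0.076), and it was more frequent than in flanking windows (exact adjusted p = 1.23e-04). Zelda passed against flanking windows (0.792% against 1.37%, exact adjusted p = 4.85e-05) and without replicate 3 (exact adjusted p = 0.0174). It did not pass with controls at the peaks' own distances from a TSS (exact adjusted p = 0.42), in windows of 50 bp or 200 bp (exact adjusted p = 0.0733 and 0.0674), in the stronger 50% of peaks (exact adjusted p = 0.591) or without replicates 1 and 2 (exact adjusted p = 0.683 and 0.0599). The other 8 motifs did not pass the threshold with matched controls, among them the TATA box with 9.93% against 10.5% (exact adjusted p = 0.268), the Su(Hw) core with 0.517% against 0.436%, the Pho core with 1.8% against 1.77% and the ETS core with 0.356% against 0.276%. The Snail-type E-box had 6.21% against 6.72%, the homeodomain core 13.5% against 14.2%, the CA repeat 4.32% against 3.89% and the poly(A) run 11.9% against 12.5%.

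Set against flanking windows, 12 motifs were more and 3 less frequent. Flanking windows were not matched on GC content or promoter class, unlike the main controls. The TATA box (7.4% of flanking windows, Fisher's exact test, adjusted p = 7.47e-12), the homeodomain core (11.3%, exact adjusted p = 5.54e-07), the initiator (16.7%) and the Su(Hw) core (0.299%, exact adjusted p = 0.0118) were then more frequent at peaks. Besides Zelda, the Snail-type E-box (9.09% of flanking windows, exact adjusted p = 7.54e-16) and the CA repeat (6.57%, exact adjusted p = 1.24e-13) were then less frequent at peaks. With controls at the peaks' own distances from a TSS, chosen after seeing the data, the TATA box was less frequent (9.93% against 11.4%, exact adjusted p = 0.00416). With windows of 50 bp the homeodomain core (6.93% against 8.05%) and the poly(A) run (5.24% against 6.71%) were less frequent (exact adjusted p = 0.00938 and 1.08e-04). The Su(Hw) and ETS cores then had odds ratios of 1.83 and 2.3 after 1.19 and 1.29, and did not pass (exact adjusted p = 0.168 and 0.0571). With windows of 200 bp the CA repeat was more frequent (10.2% against 7.53%, exact adjusted p = 6.22e-10) and the Snail-type E-box less frequent (12.4% against 13.6%, exact adjusted p = 0.0398). In the leave-one-out settings the poly(A) run was less frequent without replicates 1 and 2 (exact adjusted p = 0.0191 and 0.00923), the Su(Hw) core more frequent without replicate 1 (odds ratio 2, exact adjusted p = 0.039) and the homeodomain core less frequent without replicate 3 (exact adjusted p = 0.0139).

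Summits lay at promoters in 63.3% of thresholded peaks (5510 of 8708, 95% Clopper-Pearson interval 62.2% to 64.3%), against a mean of 13.6% when the peaks were moved by random circular shifts along their chromosome arms. The highest of the 1000 shifts gave 15.8% (one-sided permutation p = 0.001, the smallest they can give). The median summit was 168 bp from a TSS. In the strongest 8708 entries of the replicate lists the promoter share was 63.8% ± 0.776 (mean and SD, n = 3). Coding exons held 0.505% of summits against 13.1% under shifts, 3' UTRs 1.15% against 5.05%, introns 25.2% against 39.5% and intergenic DNA 8.68% against 27.3%. Each of these differed from the shifts (two-sided permutation p = 0.001 and adjusted p = 0.0014). The classes exclude each other, so the high promoter share lowers the shares of the other classes together. Summits outside promoters were not tested by themselves, so a lower share of all summits is not depletion among them. The 5' UTRs beyond the promoter, with 0.609% against 0.781%, and other exons, with 0.62% against 0.812%, did not (permutation test, adjusted p = 0.094 for both). In the stronger 50% of peaks both did, with 0.413% and 0.367% (permutation test, adjusted p = 0.008 for both), and all 7 classes then differed from the shifts. The promoter share was higher in that set as well, which again lowers the others.

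**Figure D3:**
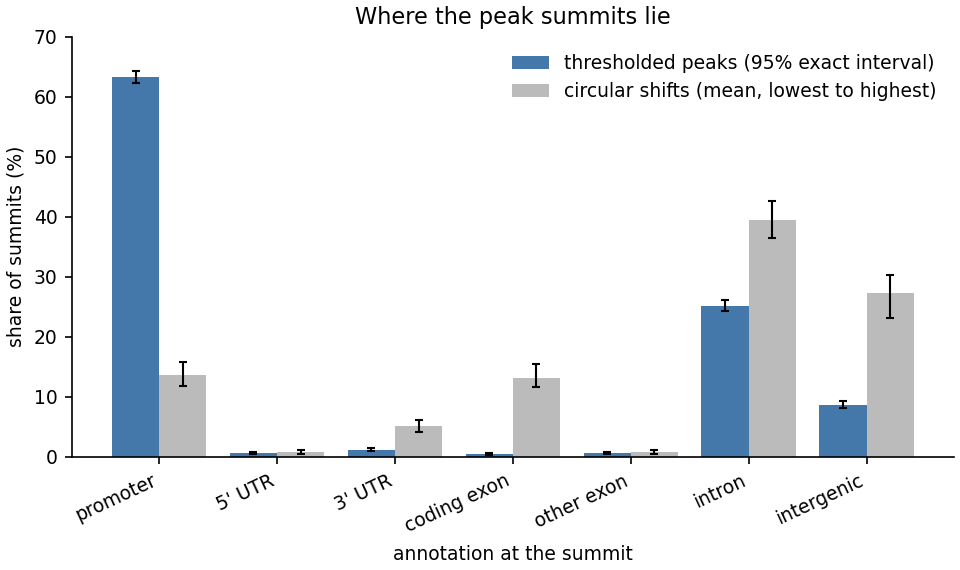
Share of thresholded summits (%) in each annotation class (bars with 95% exact binomial intervals) beside the mean over 1000 circular shifts (bars with the lowest and highest shift). Promoters hold 63.3% of the summits against 13.6% under shifts, and coding exons 0.505% against 13.1%.

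Promoter peaks were also higher. Their median signal was 273.9, against 189.2 for the 3198 peaks elsewhere, a ratio of 1.45 (permutation test of the difference in medians, two-sided p = 1e-05, the smallest 100000 resamples can give). The ratio was 1.54, 1.38 and 1.36 in the lists of replicates 1, 2 and 3. Promoters held 93% of the 200 strongest summits, 78.9% at ranks 201 to 1000, 73% at ranks 1001 to 4000 and 53.1% at ranks 4001 to 8708. Peaks within a list are not independent replicates, so these tests describe the lists.

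Of 13945 protein-coding genes on the 6 arms, 5985 (42.9%) had a thresholded summit within 500 bp of a TSS. Of the 27 gene lists fixed in advance, 9 were above and 9 below the other genes (Fisher's exact test, adjusted over the lists), and 9 did not pass. Neighbouring genes that share a promoter share its peak, so the lists were also tested without genes that have a TSS within 1000 bp of another gene's. The members left ranged from a few, such as 13 of 73 mitochondrial ribosomal protein genes, to most, such as 32 of 36 segmentation genes. The share among other protein-coding genes fell as well, to 27% beside the cytoplasmic ribosomal proteins for example.

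Of 86 cytoplasmic ribosomal protein genes, 82 had a promoter peak (95.3%, against 42.6% of other genes, odds ratio 27.6, exact adjusted p = 1.18e-24), and the replicate lists gave 94.2% ± 1.16 (SD, n = 3). The odds ratio was 13.9 in the stronger 50% of peaks, 16.3 without the 200 strongest, a setting chosen after seeing the data, and 99.9 without shared promoters, where all 18 genes left had a peak. RpS28a (signal 48442, the peak shared with Axn), RpL13A (37285), RpL35 (9204) and RpL23 (6360) had the highest signals. Glycolysis and oxidative phosphorylation followed with 39 of 42 genes (92.9%, exact adjusted p = 3.86e-11), led by SdhA (44282), the glyceraldehyde phosphate dehydrogenase gene Gapdh2 (1871), ATPsynC (1049) and Pgk (902.5). Of 32 proteasome subunit genes 25 had a peak (78.1%, exact adjusted p = 1.9e-04), with Prosalpha7 at 30490, Prosbeta7 at 2940, Prosbeta1 at 614 and Rpn6 at 566.1. Mitochondrial ribosomal protein genes had 54 of 73 (74%, exact adjusted p = 2.77e-07), led by mRpS26 (16518), mRpS21 (6445), mRpL41 (1848) and mRpS23 (1818). Without shared promoters that call ended: 4 of the 13 genes left had a peak (30.8%, against 27.2% of other genes), and the odds ratio went from 3.81 to 1.19 (exact adjusted p = 0.82).

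Trithorax group and remodeler genes had peaks at 22 of 24 (91.7%, exact adjusted p = 2.11e-06), among them Ino80 (2677), brm (1017), Acf (655.9) and polybromo (416). Without shared promoters 4 of 6 had one (66.7%, against 27.2% of other genes, odds ratio 5.36 after 14.7, exact adjusted p = 0.0972), and the call ended. The odds ratio was 8.19 at a TSS distance of 250 bp, 4.87 in the stronger 50% of peaks, and 5.17, 8.41 and 4.37 without replicates 1, 2 and 3 in peaks supported in both others. Polycomb group genes had 19 of 23 (82.6%, exact adjusted p = 3.07e-04), with ph-p at 1652, Kdm2 at 1510, Pc at 793 and Jarid2 at 549.9. Of the basal transcription machinery 25 of 30 had a peak (83.3%, exact adjusted p = 1.71e-05), with TfIIEbeta (35389) and Taf11 (18435) far above TfIIA-S (852.6) and Taf4 (677.9). Cell cycle and DNA replication genes had 30 of 37 (81.1%, exact adjusted p = 6.48e-06). The origin recognition gene Orc6 (22925), the cyclin gene CycD (12139), the helicase gene Mcm2 (11369) and Dp (785.5) were highest. The preset list of ZAD zinc finger genes had 15 of 20 (75%, exact adjusted p = 0.00803), led by ZIPIC (23730) and Zif (8728). Sry-beta and its neighbour Sry-alpha, which share 1 peak (1068), came next. Sry-alpha was entered in the list and counts among the 15, though it is not a zinc finger gene. That list missed the threshold without shared promoters, where 8 genes were left and the odds ratio was 4.47 after 4 (5 of 8, 62.5% against 27.2%, exact adjusted p = 0.0853), and without the 200 strongest peaks, a setting chosen after seeing the data (65%, exact adjusted p = 0.0591).

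Of 36 segmentation genes 6 had a promoter peak (16.7%, against 43% of other genes, exact adjusted p = 0.00192), hb at 342.5, hry at 308.2, nkd at 294.4 and bcd at 277.1 being the highest. D and Dr were among those without. Without shared promoters the call ended (6 of 32, odds ratio 0.616 after 0.265, exact adjusted p = 0.518): the share of the list was then 18.8% and that of other genes 27.2%. In peaks supported in both other replicates its share was 11.1% without replicate 2 and without replicate 3. The other lists of this paragraph did not pass the threshold at a TSS distance of 500 bp over all peaks. Among 8 homeotic genes only Dfd had a peak (2090), while Abd-B and Antp did not (exact adjusted p = 0.168); at a TSS distance of 250 bp none had one, and the list passed (exact adjusted p = 0.0377), and at 1000 bp 2 of 8 did. Dorsoventral patterning genes had 7 of 28 (25%, exact adjusted p = 0.0783). Their highest were tup (374.1), ush (257.4), pyr (223) and egr (151.8), and Doc1 and Doc2 had none. This list passed in the stronger 50% of peaks (exact adjusted p = 0.0169) and when peaks had to be supported in 2 replicates: without replicates 1, 2 and 3 its share was 10.7%, 14.3% and 7.14% (exact adjusted p = 0.00522, 0.0149 and 0.00198). Mesoderm and muscle genes had 7 of 27 (exact adjusted p = 0.105), with Msp300 at 760.6, Tm1 at 500.3, Mef2 at 468.2 and tin at 391.9, and none at the actin genes Act57B and Act87E. This list passed at 250 bp (14.8%, exact adjusted p = 0.0224) and at 1000 bp (25.9%, exact adjusted p = 0.045). Neural genes had 7 of 26 (exact adjusted p = 0.14), with brat at 1387, elav at 1168, brp at 253.3 and grh at 194.5, and none at ac or Syt1. In the stronger 50% of peaks this share fell to 11.5%, against 29.2% of other genes (exact adjusted p = 0.0665). The Notch pathway had 8 of 22 (exact adjusted p = 0.721), with Su(H) at 418, N at 411.7, numb at 384.5 and neur at 324.2, and none at E(spl)m2-BFM or E(spl)m4-BFM. In peaks supported in both other replicates its share was 18.2% without replicate 1 and without replicate 3, against 36.8% and 35.8% of other genes, and it was 7.69% without shared promoters; none of these passed.

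Of 110 cuticular protein genes only Lcp9 had a peak (202.6; 0.909% of the list, exact adjusted p = 1.18e-24). Cpr11A and Cpr100A were among those without. The share was 0% at a TSS distance of 250 bp, in the stronger 50% of peaks and without shared promoters, and 2.73% at 1000 bp. Of 119 odorant and gustatory receptor genes 3 had one (exact adjusted p = 9.13e-24): Gr97a (44916, shared with CG5521), Gr63a (258.8) and Gr21a (134.8). Gr10a and Gr10b had none. The share of this list was 0.84% at a TSS distance of 250 bp, 5.88% at 1000 bp and 1.12% without shared promoters. Of 34 testis and eggshell genes only mia had a peak (243.5, exact adjusted p = 5.58e-07), and the chorion genes Cp15 and Cp16 did not. None of 14 antimicrobial peptide genes had one (95% interval up to 23.2%, exact adjusted p = 9.51e-04), AttA and AttB included.

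None of 111 replication-dependent histone genes had a peak (interval up to 3.27%, exact adjusted p = 1.94e-26), His1:CG31617 and His1:CG33801 included. These genes lie in near-identical tandem copies, where reads cannot be assigned to 1 copy, so the absence of listed peaks is uncertain. Of 290 tRNA genes 34 had a peak within 500 bp (11.7%, exact adjusted p = 8.87e-20), such as tRNA:Tyr-GTA-1-8 (1366), tRNA:Phe-GAA-1-2 (725.2), tRNA:Trp-CCA-2-2 (624.5) and tRNA:Ala-TGC-2-1 (610.3). Of the tRNA genes, tRNA:Ala-AGC-1-1 and tRNA:Ala-AGC-2-1 had none. The share of the tRNA list stayed below that of other genes but ranged widely, with 5.86% in peaks supported in both other replicates without replicate 3, 5.17% in the stronger 50% of peaks, 6.9% at a TSS distance of 250 bp, 20.3% at 1000 bp and 0 of 69 without shared promoters. Of 269 snoRNA genes 29 had one (10.8%, exact adjusted p = 6.77e-20). Their share was 5.58% at a TSS distance of 250 bp and 31.2% at 1000 bp (exact adjusted p = 1.68e-23 and 0.00356), and 7.06% in the stronger 50% of peaks. A single peak of 1463 served snoRNA:Or-aca5 and snoRNA:Psi28S-2949. snoRNA:Psi18S-1275 had 1252 and snoRNA:Or-CD11a 844.8, while scaRNA:MeU1:95C-A24 and scaRNA:MeU1b-A234 had none. Of 32 snRNA genes 4 had one (12.5%, exact adjusted p = 0.00803), all at low signal: snRNA:7SKa 307.1, snRNA:U1:95Ca 257.1, snRNA:U4:39B 187.2 and snRNA:U2:34ABb 167.1. snRNA:7SKb and snRNA:LU had none. The snRNA share was 6.25% in the stronger 50% of peaks, and also without replicate 3 in peaks supported in both other replicates. Without shared promoters the calls of the snoRNA, snRNA and antimicrobial peptide lists ended, with few genes left. The snoRNA list had 4 of 41 (9.76% against 23.2%, odds ratio 0.36 after 0.22, exact adjusted p = 0.0853). The snRNA list had 2 of 12 (16.7% against 23.1%, odds ratio 0.66 after 0.26, exact adjusted p = 0.82). Antimicrobial peptides had 0 of 6 (exact adjusted p = 0.35). These shares were close to those of the whole lists, while the share of other genes fell.

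The remaining lists did not pass the threshold. Insulator and architectural protein genes had 14 of 22 (63.6%, exact adjusted p = 0.0775), led by ZIPIC, Zif, the chromodomain gene Chro (1954) and CTCF (1426). This list passed with a TSS distance of 250 bp (63.6%, exact adjusted p = 0.0224) or 1000 bp (77.3%, exact adjusted p = 0.00755), in the stronger 50% of peaks and, among peaks supported in both other replicates, without replicate 3 (59.1% in both, exact adjusted p = 0.00637 and 0.0361). It did not pass without the 200 strongest peaks, chosen after seeing the data (54.5%, exact adjusted p = 0.313), and without shared promoters 1 of 4 had a peak (25%, odds ratio 0.892, exact adjusted p = 1). The piRNA pathway had 16 of 28 (exact adjusted p = 0.155), with wde at 5666, papi at 709.7, cuff at 548.4 and shu at 400. It passed at 1000 bp (67.9%, exact adjusted p = 0.0454), and in the stronger 50% of peaks it had 32.1% against 29.2% of other genes. Ecdysone response genes had 10 of 23 (43.5%, exact adjusted p = 1), with usp at 1992, Hr39 at 590.9, tai at 580.3 and Eip75B at 501.6, and none at Blimp-1 or Eip74EF. The ecdysone share was 26.1% without replicate 1, in peaks supported in both others, and 28.6% without shared promoters, against 36.8% and 27.2% of other genes. Heat shock and chaperone genes had 10 of 24 (exact adjusted p = 1), with Hsp83 at 21188, Hsp27 at 898, Hsc70-5 at 837.4 and Hsp60A at 402.9, and none at CG4456 or Hsc70-1.

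**Figure D4:**
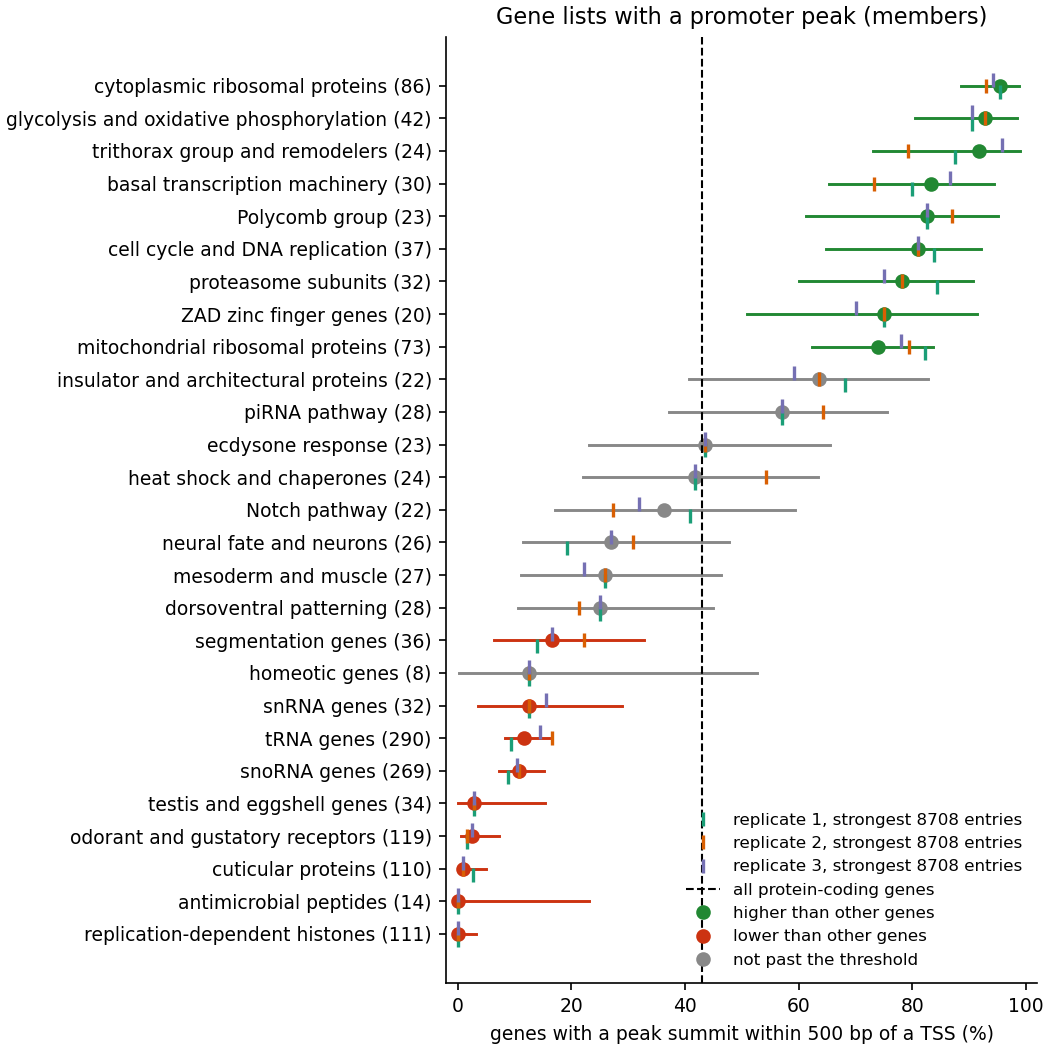
Share of each list's genes (%) with a thresholded summit within 500 bp of a TSS (points with 95% exact binomial intervals, coloured by the result of Fisher's exact test), the share in each replicate's strongest entries (ticks) and the share over all protein-coding genes (dashed line, 42.9%). Cytoplasmic ribosomal proteins reach 95.3%, while cuticular proteins stand at 0.909% and replication-dependent histones at 0%.

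A summit among the strongest 8708 entries of the replicate lay within 100 bp for 79.8% of thresholded peaks in replicate 1 (95% interval 78.9% to 80.6%), 80.2% in replicate 2 (79.3% to 81%) and 90.4% in replicate 3 (89.7% to 91%). Circular shifts gave 1.31%, 1.32% and 1.32% on average (one-sided permutation p = 0.001 for each, the smallest possible). With replicate lists of 50% of the length, which can hold no more than about that share of the peaks, support was 47.8%, 47.9% and 49.2%. All 200 strongest peaks were found in all 3 replicates. At ranks 4001 to 8708 the share found in all 3 was 37.3%, and over the whole list it was 64.2% (5593 peaks). The pooled list from which the thresholded peaks come was made from these same replicates, so the shares are not independent of the list.

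Between replicate lists, replicates 1 and 2 shared 70.2% of their strongest 8708 entries, replicates 1 and 3 74.6%, and replicates 2 and 3 75.1%. The mean over the 3 pairs was 73.3% ± 2.69 (SD). Across thresholded peaks present in both lists, the signals correlated with a Spearman's rho of 0.806, 0.826 and 0.844, a correlation across peaks and not across independent samples. The ush promoter peak ranked 3057 in replicate 1, 26340 in replicate 2 and 4794 in replicate 3, and that of Orc6 ranked 93, 76 and 87; both examples were chosen after their ranks were seen.

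Chromosome 4, a small and largely heterochromatic chromosome, carried few peaks. It held 23 thresholded summits, 0.264% of the total against 1.01% expected from its length (ratio 0.262, exact binomial test, adjusted p = 2.16e-15), and 0.371% ± 0.0928 of the strongest 8708 entries per replicate (SD, n = 3). On the X the count of 1611 was 1.05 times that expected (exact adjusted p = 0.0505). Set against protein-coding start sites, the X ratio was 1.1 (exact adjusted p = 1.96e-04) and that of chromosome 4 was 0.365. The ratios of 2L, 2R, 3L and 3R were 1.04, 1.04, 0.952 and 0.971 (exact adjusted p = 0.0999, 0.0779, 0.0505 and 0.132).

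The same reads processed on the older build dm3 gave 7563 thresholded peaks, of which 3 lay on 2RHet, 3RHet and XHet, 1 on each. The shares of the arms differed between builds by at most 0.144 percentage points, with chromosome 4 at 0.264% on dm6 and 0.185% on dm3. The 2 lists come from the same samples and are not independent evidence.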

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

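The tests on repeated sequence, on ribosomal protein genes and on the enrichment of replicate 3 had their predictions written before the result was seen; the other tests of this part were chosen after it. The design has 1 group, so no biological explanation was tested between conditions.

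Entries of the deposited pooled list that the thresholded list leaves out were also found across replicates. Of 21292 pooled entries below the threshold, 3313 (15.6%, 95% interval 15.1% to 16.1%) had a summit within 100 bp in all 3 replicate lists, against 1.41% on average under circular shifts (permutation p = 0.001, the smallest possible). Promoters held 30.9% of these entries and 22.7% of the others. What flagged it was a signal in entries that the comparisons of the report do not use. The replicates also make up the pooled list, so the share is not independent of it. The whole replicate lists were searched here, not only the strongest entries that define support of a thresholded peak. The share therefore cannot be set beside the shares of support.

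The 200 strongest peaks, such as those at CG11454 and aux, are the top of a continuous curve of heights, and what could raise them was weighed. Reads shared between annotated transposable elements or exact copies in the reference were argued against. Of the 200 summits, 0% lay in a transposable element or in a 50-base sequence found more than once (interval up to 1.83%). The prediction was 50% or more. Near-identical copies outside annotated elements, and copies missing from the reference, were not looked for. Strong pull-down at the most active promoters could not be told apart: ribosomal protein genes had an odds ratio of 1.11 among genes of these peaks against genes of the others (Fisher's exact p = 0.784), and no expression data were used here. Recognition of a sequence by the tagged protein or a partner stayed open as well. The 5 leading 8-mers of X, 2L, 2R and 4, 1 of them part of the DRE family, were 21.9 times as frequent in the strongest peaks on 3L and 3R as in control windows, but that test was chosen after the sequences had been seen on all arms and does not separate recognition from active promoters.

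The weaker peaks at promoters, such as that of hb, might follow from the same sequence or from general pull-down of open promoters. For the first, GAACYAG was in 4.05% of peaks of ranks over 1000, so most of these peaks lacked it within 100 bp of the summit. That share was above the 2.54% of their controls (odds ratio 1.62, Fisher's exact p = 1.89e-07). It was below the 50% or more predicted. That mark was written after the result was seen, so missing it decides nothing by itself. The counts, 312 of 7708 peaks against 196 of 7708 controls, argue against an exact GAACYAG match near the summit bringing most of these peaks. A part of them could still follow from it. Inexact matches were not counted, and peaks away from promoters were included. For general pull-down, promoters held 53.1% of peaks of ranks over 4000, and no list of another pull-down was there to set beside it, so it stayed open.

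Replicate 3 held more of the thresholded peaks than replicates 1 and 2. A larger weight of replicate 3 in the pooled list, or greater depth, could bring this and stayed open. Its less close pair shared 4.4 percentage points more than replicates 1 and 2 did, but a deeper replicate would also be closer to the others, so this excludes neither, and no read counts were given. The ratio of strong to weak signal was 691.6, 561.4 and 619.4 in replicates 1, 2 and 3. Replicate 3 lay between the others, at 0.896 times the higher, so this ratio did not show stronger enrichment over its own background. The weak entries of a list stand in for background and do not measure it, so stronger enrichment was not excluded.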

How the results depend on the processing

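The share of peaks at promoters kept its direction and its side of the threshold throughout, from 55.9% with a TSS distance of 250 bp to 74.2% in the stronger 50% of peaks. Promoter peaks stayed higher than others, and support in replicates stayed above the shifts under every alternative, though its value fell with shorter lists. The leave-one-out settings kept thresholded peaks supported in both remaining replicates, did not make the list again, and drew new control windows for the motifs. In them, support in the remaining replicates ranged from 67.9% to 74.1%, and the motifs less frequent at peaks numbered from 1 to 2. Leaving out shared promoters, which leaves fewer genes to test, left 5 lists below other genes. The mean agreement of replicate pairs was 80% with lists of 50% of the length, 59.4% with lists of 200% and 60.6% at 50 bp. Matches within 50 bp are a part of those within 100 bp, so agreement could not rise at that distance. The cause of the change with list length was not tested. The 8-mers past the threshold numbered 866 with all peaks and 168 with flanking windows, the arms 2 with start sites as the expectation, and the motifs less frequent at peaks 1 in the stronger 50% of peaks; the cause was not tested.

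Direction was counted as turned for 30 single results, 1 of them a tie, and the cause was not tested. The tie was the Pho core without replicate 3, with 1.89% of peaks and of controls. With flanking windows, past the threshold, the turned results were the TATA box (9.93% of peaks), the initiator (18.6%), the homeodomain core (13.5%) and the CA repeat (4.32%). None of the others was past the threshold on the turned side. They were the Pho core (1.8%) and the poly(A) run (11.9%) with flanking windows, the TATA box (5.11%) in windows of 50 bp, and in windows of 200 bp the Su(Hw) core (0.769%), the ETS core (0.563%), the homeodomain core (25.7%) and the poly(A) run (22.4%). In the stronger 50% of peaks they were the Pho core (2.07%), the CA repeat (3.15%) and heat shock genes (37.5%). In 1 or more of the leave-one-out settings, with the range over all 3, they were heat shock genes (37.5% to 41.7%), ecdysone genes (26.1% to 39.1%), the Pho core (1.82% to 1.89%), the CA repeat (3.67% to 3.84%), the Su(Hw) core (0.483% to 0.527%) and the Snail-type E-box (6.47% to 6.65%). Without shared promoters they were heat shock genes (37.5%) and insulator genes (25%), and with start sites as the expectation 2L (0.972), 2R (0.957) and 3L (1.04).

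Of 107 named genes with a promoter peak, 15 had none at 250 bp, among them Dfd, hb and Hsp83. For 7 more the peak within 250 bp was a weaker one: RpL23 (289.4), Mcm2 (5857), ph-p (126.2), Kdm2 (1223), papi (244.4), Su(H) (273.9) and grh (124.4). At 1000 bp a stronger peak came into reach of wde (36710), RpL23 (12245), Msp300 (1072), Su(H) (505.2), ush (480.9) and Lcp9 (358.1). Without replicates 1, 2 and 3, 4, 4 and 6 had none, egr and Gr21a each time. Depth is not given in the files, so peaks missed for want of reads cannot be counted. No paired analysis was possible because the series has 1 group.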

Other observations

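The analyses of this part were chosen after seeing the data. The palindrome GAACYRGTTC occurs 511 times on the 6 arms, and 146 of these copies (28.6%) lay within 100 bp of a thresholded summit. At promoters 91 of 130 copies did (70%, 95% Clopper-Pearson interval 61.3% to 77.7%), 73 of them by 1 of the 200 strongest summits. Elsewhere 55 of 381 did (14.4%). The shorter GAACYAG occurs 20107 times, with 13.9% of promoter copies and 1.26% of the others near a summit. Among the 200 strongest peaks, the 74 with the palindrome had a median signal of 25275, the 74 with GAACYAG alone 18109 and the 52 with neither 12072. The median of peaks with either was 1.89 times that of peaks with neither (permutation p = 5.4e-04). The match nearest the summit lay at a median of 23 bp in the 200 strongest peaks and 38 bp in the others.

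Start sites of diverging genes were frequent at the strongest peaks. Of the 186 promoter peaks among the 200 strongest, 47.3% (interval 40% to 54.8%) lay between diverging genes, against 29.2% of the 5324 other promoter peaks (odds ratio 2.18, Fisher's exact p = 3.23e-07). Of these 186 summits, 87.6% were upstream of the nearest TSS, against 78.6% of the others. The remaining 14 of the 200 strongest lay away from promoters. They include summits in introns of the kinesin gene Khc (2R 16270651, signal 13756) and of Dsp1 (X 16335467, 13105), in a coding exon of gukh (3R 19017477, 12224), and in an intron of the Fos homologue kay (3R 29772245, 5138). The strongest of them, with a signal of 24202, was intergenic at 3L position 12732951, 1660 bp from a TSS.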
